A study of Homo sapiens with 9 samples.

How the data were processed

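RNA sequencing was used to measure gene expression in immortalized human trabecular meshwork cells, a line made from the filtering tissue at the front of the eye through which aqueous humour drains. Per the labels, the cells were held in serum-free medium for 24 h and then given norepinephrine (NE) at 1 µM, the glucocorticoid dexamethasone (DEX) at 0.1 µM, or the vehicle DMSO for 6 h. The labels list 3 biological replicates in each of the 3 groups, 9 samples in all, and do not say whether the replicates came from separate cultures on separate days. The p-values therefore measure the spread between these samples, part of which can be technical.

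The deposited values are expected counts per gene, meaning estimated counts that need not be whole, in 2 tables of 37247 genes each. The authors placed 3 DEX libraries with 3 vehicle libraries in the first table and 3 NE libraries with 3 vehicle libraries in the second, so the tables hold 12 columns for 9 labelled samples. The unit was read from the deposited values: 49.3% to 55.6% of the values above 0 in a library were not whole, and the totals differed between libraries. The aligner, the counting tool, the genome build, the strand setting and the library kit are not given in the sources used here. The vehicle columns of the first table carry the names and numbers of the labelled vehicle samples. The vehicle columns of the second table are named for DMSO and carry the numbers 1 to 3, hold other values than the first set, and were assigned to the vehicle group without being matched to a labelled sample. They may be other cultures or the same samples sequenced or processed again, and the fit of all 12 libraries treats them as separate. The number of genes that differ between the 2 sets, given below, argues against the same libraries only sequenced again.

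Because each table has its own vehicle libraries, each treatment was tested only against the vehicle libraries of its own table, the fallback written before the data were examined. A direct test of DEX against NE was not run. In its place, the difference between the DEX effect and the NE effect (DEX minus vehicle, minus NE minus vehicle) was tested in a fit of all 12 libraries. This test, and a comparison of the vehicle libraries of the 2 tables, were added after the data were seen.

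Expected counts were rounded to whole numbers, which changed no library total by more than 0.000918%. Gene symbols were taken from a table of gene identifiers and matched 34436 of the 37247 identifiers. Chromosome positions, gene types, GC content and transcript length came from GENCODE release 29 on GRCh38, which holds 34620 of the identifiers when the version number is ignored and 33694 with the same version. Most listed genes are protein-coding genes (19745) or pseudogenes (14472), and only 10 are long intergenic or antisense RNAs.

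Genes were filtered with filterByExpr at its defaults and normalized by TMM. Differential expression was tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust dispersion and Benjamini-Hochberg adjustment, and an adjusted p below 0.05 was called. All adjusted p-values of genes come from this test unless another tool is named, are two-sided, and are given with log2 fold changes and their standard errors (SE). Levels are CPM, counts scaled to a common total by TMM-adjusted library sizes, given as mean ± SD over 3 libraries. The DEX comparison tested 15133 genes, the NE comparison 15630 and the difference between the effects 15952.

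Before the data were examined, 29 gene lists were fixed. They cover the glucocorticoid response, glucocorticoid-induced genes of trabecular meshwork, metallothioneins, cAMP and CREB targets, immediate early genes, adrenergic receptors and their regulators, cAMP signalling components, the circadian clock, phagocytosis, extracellular matrix, matrix turnover, actin cytoskeleton and contractility, TGF-beta and BMP signalling, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, the cell cycle, cholesterol synthesis, the unfolded protein and ATF4 response, hypoxia and glycolysis, and steroid receptors and chaperones. They also cover markers of trabecular meshwork, endothelial, immune, epithelial, melanocyte and Schwann, and smooth muscle and pericyte cells, mitochondrially encoded genes, ribosomal protein genes and replication-dependent histones. Lists with at least 3 tested members were tested with camera (limma 3.58.1), which asks whether a list's genes moved more than the other genes, at the preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. The same test with an inter-gene correlation estimated from the data was an alternative. Fry, planned beside camera, asks whether a list as a whole moved one way, and its calls are given with the other settings. A list of 10 target and feedback genes of the ERK pathway was added after the NE results were seen.

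The rule for named genes was also fixed beforehand. It takes the 8 highest and the 8 lowest log2 fold changes among called genes with an average log2 CPM of at least 1, a gene symbol and non-overlapping groups. For the difference between the effects the rule takes 5 in each direction, where the condition on groups was not applied. It adds up to 3 called members of each list with the smallest adjusted p, and the fixed genes FKBP5, TSC22D3, ZBTB16, PER1, MYOC, ANGPTL7, NR3C1, ADRB1, ADRA1B, NR4A1, FOS and IL6, whether or not they pass. Some genes that the rule takes are not reported here. For genes called in both treatments it takes the 5 with the smallest larger-of-both adjusted p in the same direction and the first 5 in opposite directions. Genes named outside this rule are said to be chosen after their values were seen.

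Whether replicate numbers pair libraries was checked by correlating, across genes with an average log2 CPM above 3, the deviations of libraries from their group means. In the DEX table the same-numbered pairs gave -0.281, -0.024 and -0.236, so the numbers do not pair them. In the NE table they gave 0.689, 0.267 and 0.476, all above the bound of 0.1 set beforehand. The vehicle numbers there come only from the column names, no label ties them to the NE samples, and vehicle 2 correlated more with NE replicate 3 (0.346) than with NE replicate 2. Vehicle 3 with NE replicate 2 (0.149) was also above the bound, so the check does not tell the pairing of numbers 2 and 3 from the swapped one. Deviations from a mean of 3 libraries cancel, so one shared by the libraries numbered 1 alone pushes the correlations among numbers 2 and 3 upward. Those correlations are therefore not separate evidence of pairing. Values with the replicate number as a block are given beside NE results where they change a call or move a count by over 1.5 times. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 2.93 to 20.86), so none was taken as a duplicate and each counted as a replicate. This check cannot show whether libraries came from separate cultures.

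Library totals ran from 19326830 to 27337259 counts in the DEX table and from 31104094 to 36216506 in the NE table. The steps were tested on data simulated from the real means, library sizes and dispersions with 200 changed genes, 50 at each fold change. The changed genes were drawn from genes above a set vehicle level, so recovery of genes with few counts was not measured. The simulated libraries held no deviations shared by replicate number and no GC trends, so these shares may not hold for the NE table. At 1.5-fold, the quasi-likelihood test recovered 90% of the changed genes in the DEX design (15133 genes), 80% in the NE design (15630 genes) and 66% for the difference between the effects (15952 genes). At 2-fold it recovered 96%, 94% and 88%. False calls made up 6.8%, 7.5% and 4.9% of all calls in these simulations.

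Alternatives fixed beforehand were median-ratio size factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, the replicate block, leaving out each library, and for lists the estimated correlation. Fitting only the compared groups, also fixed beforehand, equals the fit within a table that was used. A fit of all 12 libraries, a correction of library-wise trends on GC content and transcript length, the replicate block combined with that correction, and the block combined with the estimated correlation were added after the data were seen. Figures were drawn with matplotlib. A member of the matrix turnover list and a member of the immune cell list were not analysed here.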

Results

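The data were expression profiles of immortalized human trabecular meshwork cells after 6 h of dexamethasone (DEX, a synthetic agonist of the glucocorticoid receptor), norepinephrine (NE, the agonist of adrenergic receptors released by sympathetic nerves) or vehicle. They address how a stress hormone analogue and a sympathetic transmitter change gene expression in cells of the aqueous outflow tissue. There were 3 DEX libraries with 3 vehicle libraries (19326830 to 27337259 counts each) and 3 NE libraries with 3 other vehicle libraries (31104094 to 36216506 counts each). The first principal component of all 12 libraries, with 49.7% of the variance, separated the 2 tables. Because each table has its own vehicle libraries, each treatment was compared only with those of its own table, by the fallback written beforehand.

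The receptors themselves were measured first as background. NR3C1, which encodes the glucocorticoid receptor, was present at 83.9 ± 4.3 CPM with vehicle and 79.6 ± 2.0 CPM with DEX (SD, n = 3 each; adjusted p = 0.377), and at 126 ± 8.2 CPM and 119 ± 5.3 CPM in the NE table (adjusted p = 0.588). It was called lower with DEX after the GC and length correction (log2 fold change -0.14), and with NE when that correction was combined with the replicate block (-0.11), so neither outcome is firm. Adrenergic receptor transcripts were low. ADRA1B was at 0.837 ± 0.15 CPM with vehicle and 0.507 ± 0.088 CPM with NE (adjusted p = 0.207), and ADRB1 at 0.306 ± 0.12 and 0.389 ± 0.016 CPM (adjusted p = 0.729). With DEX, ADRA1B had a log2 fold change of 0.80 (SE 0.28, adjusted p = 0.091) and was called without a filter on low counts (0.80). ADRB1 was not tested in the DEX table, where it had 1 to 6 counts per library.

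DEX raised a set of well-known glucocorticoid targets within 6 h. TSC22D3, which encodes the anti-inflammatory protein GILZ (chromosome X, 107713221 to 107777342, GRCh38), rose 13.2-fold, from 7.76 ± 0.66 to 103 ± 5.0 CPM (log2 fold change 3.73, SE 0.07, adjusted p = 1.99e-13). SERPINA3, a secreted serine protease inhibitor (chromosome 14, 94612377 to 94624055), rose 10.6-fold from 0.516 ± 0.22 to 5.55 ± 0.85 CPM (adjusted p = 2.09e-07). The clock gene PER1 (chromosome 17, 8140472 to 8156506) rose 4.85-fold to 127 ± 9.5 CPM (adjusted p = 4.14e-11), and FKBP5, a chaperone that restrains the receptor (chromosome 6, 35573585 to 35728583), rose 2.99-fold from 124 ± 6.7 to 370 ± 8.6 CPM (adjusted p = 4.97e-11). Among genes with a symbol, an average log2 CPM of at least 1 and non-overlapping groups the largest falls were in cytokines: IL11 fell by 1.57 on the log2 scale (SE 0.14, from 27.4 ± 4.8 to 9.20 ± 0.77 CPM), the chemokine CXCL12 fell by 1.55 (SE 0.20) and IL1B fell by 1.36 (SE 0.14), with adjusted p of 9.45e-05, 0.000105 and 6.98e-05.

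By the same limits the other genes with the largest increases after DEX were the potassium channel KCNH5 (6.59-fold), the cell-cycle regulator RGCC (6.39-fold), the serotonin receptor HTR1B (5.03-fold), the transcription factor KLF15 (4.90-fold) and the integrin ITGA10 (4.79-fold), with adjusted p from 2.58e-08 to 2.77e-05. ZBTB16, a transcription factor induced by glucocorticoids, rose 6.38-fold from 0.290 ± 0.029 to 1.87 ± 0.33 CPM (adjusted p = 1.53e-05). The other genes with the largest decreases by these limits were the cation channel TRPC4, TAGLN3, the chemokine CCL2, TENT5C and TNFAIP2, which fell by 1.16, 1.12, 1.09, 1.02 and 1.00 on the log2 scale (SE 0.18, 0.13, 0.08, 0.09 and 0.12). CCL2 went from 86.3 ± 8.1 to 40.6 ± 4.1 CPM (adjusted p = 2.47e-05). MYOC and ANGPTL7, genes that rise in trabecular meshwork cultures under glucocorticoids, had at most 6 and 11 counts per library in the DEX table and were not tested. NR4A1 (log2 fold change -0.01, SE 0.11, adjusted p = 0.962), FOS (0.34, SE 0.10, adjusted p = 0.0683) and IL6 (-0.63, SE 0.20, adjusted p = 0.0742) did not pass. FOS was called without DEX replicate 3 or vehicle replicate 1 (0.44 and 0.42), and IL6 without DEX replicate 1 (-0.80). Both were also called by DESeq2 (0.34 and -0.63) and without a filter on low counts (0.35 and -0.63), and FOS in the fit of all 12 libraries (0.34), so neither outcome is firm.

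In all, edgeR's quasi-likelihood test called 1530 of 15133 genes after DEX, 1006 higher and 524 lower, of which 123 rose and 20 fell by more than 2-fold. The 20 were 31 without vehicle replicate 1, 67 without a filter on low counts, 11 with a stricter one and 13 with DESeq2. Without DEX replicate 2 the count was 994 and without vehicle replicate 2 it was 983. Correcting GC content and length trends changed the split to 1074 higher and 919 lower.

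**Figure D1:**
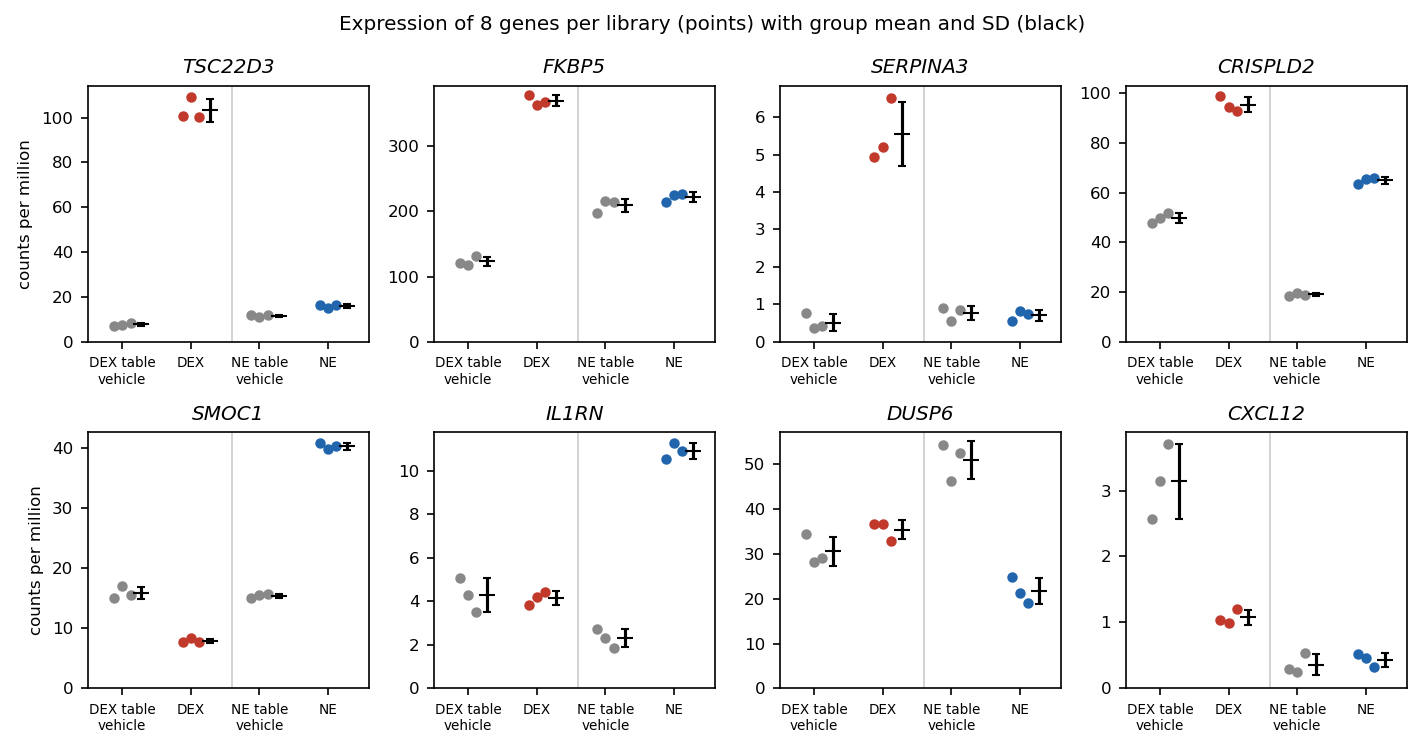
Expression of 8 genes in CPM (linear axes from 0). Each coloured or grey point is a library, the black bar is the mean and the error bar the SD of 3 libraries, and the vertical line parts the tables. TSC22D3 was at 7.76 CPM with vehicle and 103 CPM with DEX. SMOC1 went from 15.9 CPM with vehicle to 7.93 CPM with DEX, and in the NE table from 15.4 CPM with vehicle to 40.3 CPM with NE.

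Of the 23 tested genes on the list of the glucocorticoid response, 20 rose after DEX, 1 fell and 2 did not pass, with a median log2 fold change of 0.93 (20 up and 1 down adjusted over the list alone; camera adjusted p = 7.91e-149, and adjusted p = 0.000688 with an estimated correlation). Of 10 tested glucocorticoid-induced genes of trabecular meshwork, 6 rose, 0 fell and 4 did not pass (8 up adjusted over the list alone; camera adjusted p = 5.35e-54, and adjusted p = 0.00113 with an estimated correlation). GAS1, which encodes a growth-arrest membrane protein, was among them and rose 1.99-fold (SE 0.06 on the log2 scale, adjusted p = 2.3e-08). These 2 lists share FKBP5, TSC22D3, ZBTB16 and MAOA, and they were the only lists of the DEX comparison still called with an estimated correlation.

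Metallothioneins, metal-binding proteins, rose in 3 of 6 tested members (5 adjusted over the list alone; camera adjusted p = 2.58e-07, adjusted p = 0.273 with an estimated correlation). MT1E rose 1.92-fold, MT2A 1.85-fold and MT1X 1.78-fold (adjusted p = 4.53e-06, 0.00449 and 0.000356). Members of this family have near-identical sequences, so the split of their counts is uncertain. In the circadian clock list 9 of 23 genes rose and 1 fell (10 up and 1 down adjusted over the list alone; camera adjusted p = 2.91e-05, adjusted p = 0.322 with an estimated correlation). NPAS2 rose 1.92-fold (adjusted p = 7.44e-05), and the repressor BHLHE40 fell by 0.61 on the log2 scale (SE 0.06, adjusted p = 4.59e-06).

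Extracellular matrix genes rose in 12 of 36 members after DEX and fell in 0 (14 up adjusted over the list alone; camera adjusted p = 7.82e-06, adjusted p = 0.332 with an estimated correlation). Thrombospondin 1 (THBS1) rose 1.56-fold from 114 ± 2.5 to 178 ± 0.95 CPM (adjusted p = 6.42e-08), fibronectin (FN1) 1.28-fold from 6310 ± 490 to 8100 ± 580 CPM (adjusted p = 0.00262) and laminin alpha 4 (LAMA4) 1.21-fold (adjusted p = 0.0013). In the TGF-beta and BMP list 10 of 29 genes rose and 1 fell (12 up and 6 down adjusted over the list alone; camera adjusted p = 0.000473, adjusted p = 0.322 with an estimated correlation). Its member LTBP1, which binds latent TGF-beta in the matrix, rose 1.97-fold (adjusted p = 1.72e-08), CCN2 rose 1.51-fold (adjusted p = 1.05e-07) and the co-receptor TGFBR3 rose 1.38-fold (adjusted p = 5.98e-05).

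Members of the immediate early and cAMP lists went both ways after DEX. Of 29 immediate early genes 10 rose and 6 fell (13 up and 8 down adjusted over the list alone; camera adjusted p = 4.23e-06, adjusted p = 0.407 with an estimated correlation), and MYC rose 1.80-fold and DUSP5 1.95-fold (adjusted p = 1.16e-08 and 5.69e-08). Of 20 cAMP and CREB targets 5 rose and 3 fell (6 up and 4 down adjusted over the list alone; camera adjusted p = 2.18e-06, adjusted p = 0.332 with an estimated correlation). They included RGS2, a regulator of G protein signalling, which rose 3.50-fold (adjusted p = 2.26e-09), and the phosphodiesterase PDE4D, which rose 2.02-fold (adjusted p = 0.000131). PER1 and DUSP1, both called higher with DEX, are also on the list of the glucocorticoid response. The cAMP and CREB list was not tested with DEX without them. Among adrenergic receptors and their regulators 2 of 13 rose and 1 fell (3 up and 1 down adjusted over the list alone; camera adjusted p = 0.0385, adjusted p = 0.322 with an estimated correlation). RGS2 and monoamine oxidase A (MAOA, 1.85-fold, adjusted p = 0.000744) were the genes that rose. That list's call ended without vehicle replicate 3, DEX replicate 1 or DEX replicate 2 (adjusted p = 0.146, 0.0599 and 0.0593).

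The list of inflammatory cytokines and NF-kB targets fell after DEX, with 9 of 23 genes lower and 2 higher (13 down and 5 up adjusted over the list alone; camera adjusted p = 4.23e-06, adjusted p = 0.322 with an estimated correlation). IL1B and CCL2 fell, whereas NFKBIA, which encodes an inhibitor of NF-kB, rose 1.57-fold (adjusted p = 3.23e-06). Among 26 interferon-stimulated genes 4 fell and 0 rose (4 down adjusted over the list alone; camera adjusted p = 4.4e-06, adjusted p = 0.479 with an estimated correlation), led by IRF1, which fell by 0.53 on the log2 scale (SE 0.05, adjusted p = 4.12e-06), and OASL, which fell by 0.67 (SE 0.08, adjusted p = 5.91e-05). Of 30 cell cycle genes 6 fell and 0 rose (7 down adjusted over the list alone; camera adjusted p = 0.00042, adjusted p = 0.322 with an estimated correlation), each by little: AURKA fell by 0.27 (SE 0.04) and CCNB1 by 0.22 (SE 0.05).

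Camera called 4 more lists after DEX. Cholesterol synthesis genes fell in 4 of 24 members and rose in 1 (camera adjusted p = 0.024, adjusted p = 0.322 with an estimated correlation), ribosomal protein genes fell in 1 of 78 (0.000127, adjusted p = 0.723 with an estimated correlation), replication-dependent histones in 2 of 35 (0.024, adjusted p = 0.322 with an estimated correlation) and epithelial markers in 1 of 6, KRT18 (0.024, adjusted p = 0.322 with an estimated correlation). Adjusted over the list alone, these lists had 6, 0, 2 and 1 lower genes, and cholesterol synthesis had 1 higher gene. The cholesterol call ended without vehicle replicate 1 (adjusted p = 0.0612) or DEX replicate 2 (0.0509), and the ribosomal and histone calls without vehicle replicate 1 (0.0634 and 0.0592). The epithelial call ended without any of 5 libraries, vehicle 1, 2 or 3 or DEX 1 or 2 (adjusted p = 0.079, 0.0553, 0.109, 0.0811 and 0.0593). Ribosomal protein genes and histones share reads with near-identical copies, so their single values are uncertain.

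The remaining lists did not pass with DEX. Camera adjusted p was 0.4 for cAMP signalling components, 0.226 for phagocytosis, 0.437 for matrix turnover, 0.246 for actin cytoskeleton and contractility, 0.854 for the unfolded protein and ATF4 response, 0.589 for hypoxia and glycolysis and 0.242 for steroid receptors and chaperones. It was 0.87 for trabecular meshwork markers, 0.938 for endothelial markers, 0.87 for melanocyte and Schwann markers, 0.87 for smooth muscle and pericyte markers and 0.87 for mitochondrially encoded genes, and immune cell markers had 2 tested members and no test. Single members did change: tissue plasminogen activator (PLAT) rose 1.68-fold (adjusted p = 1.66e-05), urokinase (PLAU) fell by 0.66 on the log2 scale (SE 0.09, adjusted p = 0.000816), the small GTPase RHOB rose 1.52-fold (adjusted p = 1.68e-06) and the forkhead factor FOXC2 rose 2.15-fold (adjusted p = 0.000433).

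NE raised targets of cAMP and CREB and lowered many immediate early genes. IL1RN, which encodes the interleukin-1 receptor antagonist (chromosome 2, 113107214 to 113134016), rose 4.76-fold from 2.30 ± 0.42 to 10.9 ± 0.37 CPM (log2 fold change 2.25, SE 0.12, adjusted p = 0.000117). The glycosyltransferase gene GALNT15 rose 3.90-fold (adjusted p = 8.49e-05), the secreted protein gene CRISPLD2 (chromosome 16, 84819984 to 84920768) 3.41-fold to 64.9 ± 1.3 CPM (adjusted p = 2.51e-06) and the orphan receptor NR4A3 3.05-fold (adjusted p = 0.000332). The phosphatase DUSP6 (chromosome 12, 89347232 to 89353271), which switches off ERK, fell by 1.23 on the log2 scale (SE 0.10) from 51.0 ± 4.2 to 21.7 ± 2.9 CPM (adjusted p = 0.000576). SPRY4, another restraint on growth-factor signalling, fell by 1.20 (SE 0.08, adjusted p = 0.000318), and cyclin D1 (CCND1) fell by 1.04 (SE 0.08) from 406 ± 27 to 198 ± 18 CPM (adjusted p = 0.000346).

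Next in size after NE, among genes with a symbol, an average log2 CPM of at least 1 and non-overlapping groups, were rises of the calcineurin-regulated factor NFATC2 (2.89-fold), PTPRN (2.82-fold), the matrix protein SMOC1 (2.61-fold, adjusted p = 1.14e-05) and the ephrin receptor EPHA5 (2.56-fold). The other largest decreases by these limits were in the transcription factors FOSL1, EGR1, JUN and POU2F2, which fell by 1.06, 1.05, 1.03 and 1.02 on the log2 scale (SE 0.05, 0.09, 0.05 and 0.11), with adjusted p from 4.87e-05 to 0.00197. The keratin-associated gene KRTAP2-3 fell by 1.08 (SE 0.15, adjusted p = 0.00787), a call that ended without NE replicate 2 (log2 fold change -1.06) and in the fit of all 12 libraries, and it has close copies. FKBP5 had a log2 fold change of 0.09 (SE 0.05, adjusted p = 0.506), TSC22D3 rose 1.38-fold (adjusted p = 0.0078, a call that ended without NE replicate 3, log2 fold change 0.44) and PER1 rose 1.90-fold (adjusted p = 0.000486). NR4A1, FOS, IL6 and ZBTB16 did not pass, with log2 fold changes of 0.31, -0.15, 0.74 and 1.32 (SE 0.07, 0.11, 0.21 and 0.31) and adjusted p of 0.0619, 0.642, 0.137 and 0.074. With the replicate block NR4A1, IL6 and ZBTB16 were called higher (adjusted p = 0.0284, 0.0254 and 0.00448). Without the block, the GC and length correction also called NR4A1 (0.32) and ZBTB16 (1.32), and ZBTB16 was called without a filter on low counts (1.32) and in the fit of all 12 libraries (1.32). MYOC and ANGPTL7, at most 5 and 8 counts per library, were not tested.

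In all, 441 of 15630 genes were called after NE, 232 higher and 209 lower, of which 59 rose and 10 fell by more than 2-fold. Those 59 were 25 to 57 with single libraries left out, 37 with a stricter filter on low counts, 83 with the replicate block and 92 with the block and the GC and length correction. The 10 were 6 without NE replicate 3, 18 with the replicate block and 20 with the block and the GC and length correction. With the replicate number as a block the count was 1688 (793 higher and 895 lower), and 439 of the 441 genes were called there in the same direction. Without NE replicate 1, 2 or 3 the counts were 275, 150 and 160, and without vehicle replicate 1, 2 or 3 they were 658, 217 and 210. Vehicle replicate 1 stood apart from the other vehicle libraries of this table (chi-square per degree of freedom 17.09 and 20.86, against 2.93 between those). Ribosomal protein genes held 6.42% of its counts against 5.4% and 5.33%, and NE replicate 1 was also raised (6.0% against 5.43% and 5.32%).

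Of 20 cAMP and CREB targets 9 rose after NE and 0 fell, with a median log2 fold change of 0.48 (15 up and 1 down adjusted over the list alone; camera adjusted p = 5.97e-31, and adjusted p = 0.00359 with an estimated correlation). PDE4D, which breaks down cAMP, rose 2.30-fold from 17.3 ± 0.38 to 39.8 ± 0.71 CPM (adjusted p = 2.41e-05). Among cAMP signalling components 6 of 31 rose and 0 fell (8 up adjusted over the list alone; camera adjusted p = 9.31e-09, adjusted p = 0.153 with an estimated correlation). Besides PDE4D these included the phosphodiesterases PDE7B (1.66-fold) and PDE3A (1.64-fold), with adjusted p of 0.000339 and 0.000373. Immediate early genes went the other way, with 12 of 29 lower and 4 higher (17 down and 6 up adjusted over the list alone; camera adjusted p = 2.18e-19, and adjusted p = 0.0437 with an estimated correlation). JUN went from 137 ± 4.7 to 67.5 ± 2.0 CPM, whereas ATF3 rose 1.83-fold (adjusted p = 0.000229).

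The list of the glucocorticoid response rose with NE as well, with 8 of 24 members higher, 2 lower and 14 not passing (10 up and 3 down adjusted over the list alone; median log2 fold change 0.20; camera adjusted p = 1.61e-27, and adjusted p = 0.00359 with an estimated correlation). CRISPLD2, DDIT4 (2.04-fold, adjusted p = 8.69e-05) and PER1 led it. The list of glucocorticoid-induced genes of trabecular meshwork had 2 of 10 higher and 0 lower (3 up adjusted over the list alone; camera adjusted p = 0.0118, adjusted p = 0.181 with an estimated correlation, and 0.0513 with the replicate block). The 3 lists still called with an estimated correlation were those of the glucocorticoid response, cAMP and CREB targets, and immediate early genes. None was called with both the block and an estimated correlation (adjusted p = 0.117, 0.117 and 0.192).

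Extracellular matrix genes were lower after NE in 4 of 36 members and higher in 0 (6 down adjusted over the list alone; camera adjusted p = 0.0103, adjusted p = 0.511 with an estimated correlation). THBS1 fell by 0.62 on the log2 scale (SE 0.07, adjusted p = 0.002) and the collagen cross-linking enzyme LOXL1 had a log2 fold change of -0.33 (SE 0.04, adjusted p = 0.00575), a call that ended without NE replicate 2. The list's call ended without vehicle replicate 3 (adjusted p = 0.147) or NE replicate 1 (0.084). Matrix turnover genes were lower in 3 of 20 and higher in 0 (7 down and 1 up adjusted over the list alone; camera adjusted p = 0.000636, adjusted p = 0.103 with an estimated correlation), and the protease gene ADAMTS1 fell by 0.55 (SE 0.05, adjusted p = 0.00079). TGF-beta and BMP genes were higher in 6 of 29 and lower in 1 (12 up and 4 down adjusted over the list alone; camera adjusted p = 0.000636, adjusted p = 0.153 with an estimated correlation). The ligand BMP6 rose 6.16-fold from 0.531 ± 0.13 to 3.30 ± 0.52 CPM (adjusted p = 0.000576).

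Inflammatory cytokines and NF-kB targets were lower in 5 of 25 members after NE and higher in 0 (8 down and 2 up adjusted over the list alone; camera adjusted p = 0.00406, adjusted p = 0.282 with an estimated correlation, and 0.0648 without NE replicate 3). The adhesion molecule VCAM1 fell by 0.97 on the log2 scale (SE 0.12, adjusted p = 0.00464). Interferon-stimulated genes were higher in 3 of 26 (5 adjusted over the list alone; camera adjusted p = 0.00174, adjusted p = 0.392 with an estimated correlation). The calls of all 3 (OASL, IFIT2 and OAS1) ended without NE replicate 2 or 3 or without vehicle replicate 2 or 3. Unfolded protein and ATF4 response genes were higher in 2 of 21 (3 adjusted over the list alone; camera adjusted p = 0.00096, adjusted p = 0.337 with an estimated correlation), and the cystine transporter SLC7A11 rose 1.43-fold (adjusted p = 0.00452). Among adrenergic receptors and their regulators RGS4 and GRK5 were lower and RGS2 higher of 14 tested (4 down and 1 up adjusted over the list alone; camera adjusted p = 0.0457, adjusted p = 0.337 with an estimated correlation). RGS4 fell by 0.71 (SE 0.05, adjusted p = 0.000346) and RGS2 rose 1.86-fold (adjusted p = 0.000576). GRK5 had a log2 fold change of -0.24 (SE 0.05, adjusted p = 0.043), a call that ended without any of the NE libraries or without vehicle replicate 2 or 3. The adrenergic list's call ended without vehicle replicate 1, 2 or 3 or NE replicate 2 (adjusted p = 0.105, 0.0507, 0.0556 and 0.183).

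Mitochondrially encoded genes passed the list test with NE (1 of 13 higher, 3 adjusted over the list alone; camera adjusted p = 1.64e-05, adjusted p = 0.253 with an estimated correlation), and their share of counts was 1.40% to 1.52% in the vehicle libraries and 1.6% to 1.67% in the NE libraries. In the DEX table this share was 3.61% to 3.92%. Cholesterol synthesis had 1 of 24 lower (camera adjusted p = 0.037, adjusted p = 0.253 with an estimated correlation), steroid receptors and chaperones 0 of 15 (0.0401, adjusted p = 0.467 with an estimated correlation) and epithelial markers 2 of 5 (0.00406, adjusted p = 0.209 with an estimated correlation). Adjusted over the list alone the lower genes numbered 1, 0 and 2. The first of these calls ended without vehicle replicate 1 (adjusted p = 0.0712) or NE replicate 2 (0.0905), and the second without the same libraries (0.219 and 0.1).

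The other lists did not pass with NE. Camera adjusted p was 0.0587 for metallothioneins, 0.0957 for the circadian clock, 0.0993 for phagocytosis, 0.0627 for actin cytoskeleton and contractility, 0.181 for the cell cycle, 0.349 for hypoxia and glycolysis, 0.0756 for ribosomal protein genes and 0.172 for replication-dependent histones. It was 0.198 for trabecular meshwork markers, 0.772 for endothelial, 0.742 for immune, 0.503 for melanocyte and Schwann, and 0.241 for smooth muscle and pericyte markers. With the replicate block metallothioneins (0.0322), actin cytoskeleton and contractility (0.0155) and ribosomal protein genes (0.000391) were called lower. Leaving out single libraries brought 6 of these lists under the threshold: metallothioneins without vehicle replicate 2 or 3 or NE replicate 1 (0.0373, 0.00808 and 0.0324), the clock without vehicle replicate 2 (0.0322), actin without vehicle replicate 1 or NE replicate 3 (0.0278 and 0.0173), phagocytosis and the cell cycle without vehicle replicate 1 (0.0402 and 0.0281), and ribosomal protein genes. These were called higher without vehicle replicate 1 (0.0138) and lower without vehicle replicate 2 or 3 or NE replicate 1 (0.00111, 0.000131 and 6.17e-05), so no direction is given for them. Metallothioneins, actin and phagocytosis genes were lower in those calls, and the clock and the cell cycle higher. RHOB, in the actin list, rose 1.27-fold (adjusted p = 0.00403).

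**Figure D2:**
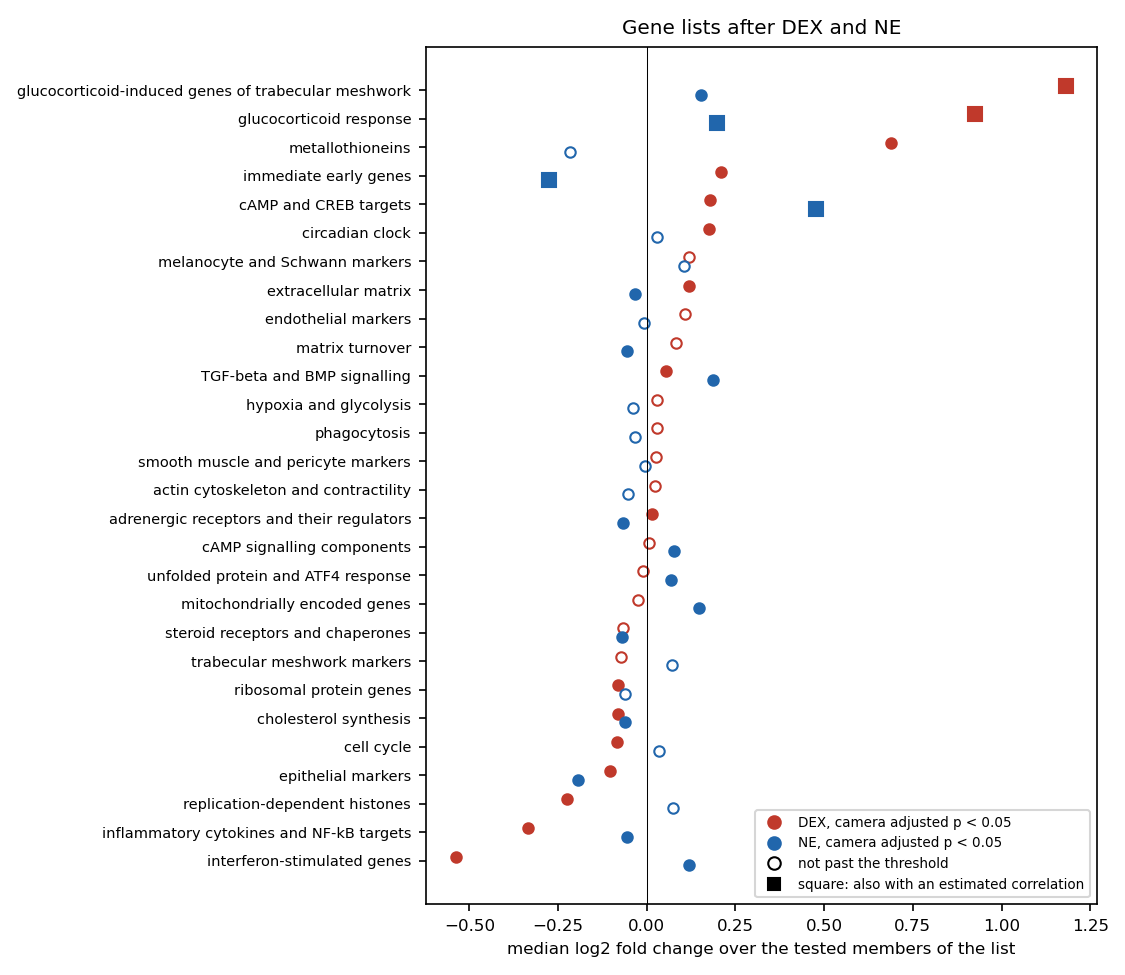
Median log2 fold change of the tested members of each gene list after DEX (red) and NE (blue). Only lists with at least 3 tested members in both comparisons are drawn, which leaves out immune cell markers. Filled symbols mark lists called by camera, and squares mark those also called with an estimated correlation. The median of the immediate early genes was 0.21 with DEX and -0.28 with NE.

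The effects of the 2 treatments differed in 957 of 15952 genes, 619 with a higher and 338 with a lower log2 fold change under DEX than under NE. As the vehicle libraries of the 2 tables also differed, a response that depends on the state of the cells in each table cannot be told apart from a difference between the treatments in these genes. Among genes with a symbol and an average log2 CPM of at least 1 the difference was largest upward for TSC22D3 (3.26, SE 0.09, adjusted p = 1.25e-10), the monocarboxylate transporter SLC16A12 (2.51, SE 0.27), the pattern-recognition protein PTX3 (2.43, SE 0.17), the protease-activated receptor F2RL1 (2.40, SE 0.22) and ITGA10 (2.36, SE 0.21). By the same limits it was largest downward for SMOC1 (-2.38, SE 0.08, adjusted p = 8.72e-10), IL1RN (-2.29, SE 0.20), NR4A3 (-2.12, SE 0.17), EPHA5 (-2.07, SE 0.24) and PTPRN (-2.02, SE 0.20). FKBP5 (1.49, SE 0.07, adjusted p = 1.75e-08) and PER1 (1.35, SE 0.10, adjusted p = 1.62e-06) responded more to DEX, and the difference did not pass for NR3C1, ADRB1, NR4A1, FOS and ZBTB16 (adjusted p from 0.0911 to 0.985). ZBTB16 was called without vehicle replicate 1 of the NE table (1.65) and FOS without DEX replicate 3 (0.59) or with the replicate block (0.48). For IL6 it was -1.37 (SE 0.31, adjusted p = 0.0162), a call that ended without NE replicate 3 (-1.28) or vehicle replicate 2 of the NE table (-1.22). For ADRA1B it was 1.51 (SE 0.38, adjusted p = 0.0284), a call that ended without any of 8 of the 12 libraries (1.27 to 1.54). The glucocorticoid response (15 of 25 higher and 2 lower, adjusted p = 6.89e-06 with an estimated correlation) and the glucocorticoid-induced genes of trabecular meshwork (5 of 11 higher and 0 lower, adjusted p = 2.71e-05 with an estimated correlation) differed as lists. Immediate early genes were higher with DEX than with NE in 14 of 30 and lower in 3 (camera adjusted p = 3.04e-21, adjusted p = 0.0581 with an estimated correlation). The other 15 lists that camera called for the difference had adjusted p from 0.0951 to 0.558 with an estimated correlation, and 11 lists were not called (camera adjusted p from 0.244 to 0.963). Single libraries ended the calls of cAMP and CREB targets (DEX-table vehicle 1, DEX 3 or NE 1 left out, adjusted p = 0.107, 0.42 and 0.0528), cAMP signalling components (DEX-table vehicle 3, NE-table vehicle 1 or NE 3, adjusted p = 0.0953, 0.145 and 0.053), inflammatory genes (DEX-table vehicle 1 or 2, DEX 3, NE-table vehicle 2 or NE 1, adjusted p = 0.104, 0.0549, 0.134, 0.123 and 0.143) and the unfolded protein response (DEX-table vehicle 1, DEX 3, NE-table vehicle 2 or 3 or NE 1, adjusted p = 0.0599, 0.0621, 0.0545, 0.0673 and 0.053). Ribosomal protein genes were called lower without DEX-table vehicle 3, NE-table vehicle 1 or NE 3 (adjusted p = 0.00753, 7.47e-06 and 0.0213).

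Of 14943 genes tested in both comparisons, 137 were called in the same direction by DEX and NE, where independent lists of these sizes would share 21.6, and 61 in opposite directions, where independent lists would share 21.4. These expected numbers assume that every gene is equally likely to be called. Genes with more counts or less spread are called more readily in both comparisons, so the expected numbers can be too low. A planned simulation of unchanged groups for this overlap is not reported here. No vehicle column was shared between the comparisons. The labels do not say whether the second set are other cultures or the labelled vehicle samples sequenced or processed again, and in that case the lists would not be independent. Of the same-direction genes 73 rose and 64 fell with both. The 5 leading ones were CRISPLD2 (1.92-fold higher with DEX and 3.41-fold with NE), GALNT15 (2.20-fold and 3.90-fold), DDIT4 (1.55-fold and 2.04-fold), PDE4D (2.02-fold and 2.30-fold) and FOSL1, which fell by 0.65 (SE 0.06) with DEX and fell by 1.06 (SE 0.05) with NE. Log2 fold changes correlated weakly across genes (Pearson 0.10, Spearman 0.13), and genes are not independent replicates. Without vehicle replicate 1 of the NE table these correlations were 0.04 and -0.01. With the replicate block the counts were 241 and 113, where independent lists would share 56.7 and 60.4. Leaving out single libraries moved the same-direction count beyond 1.5 times for NE replicate 2 (59) and 3 (68) and vehicle replicate 2 (81) and 3 (85) of the NE table.

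**Figure D3:**
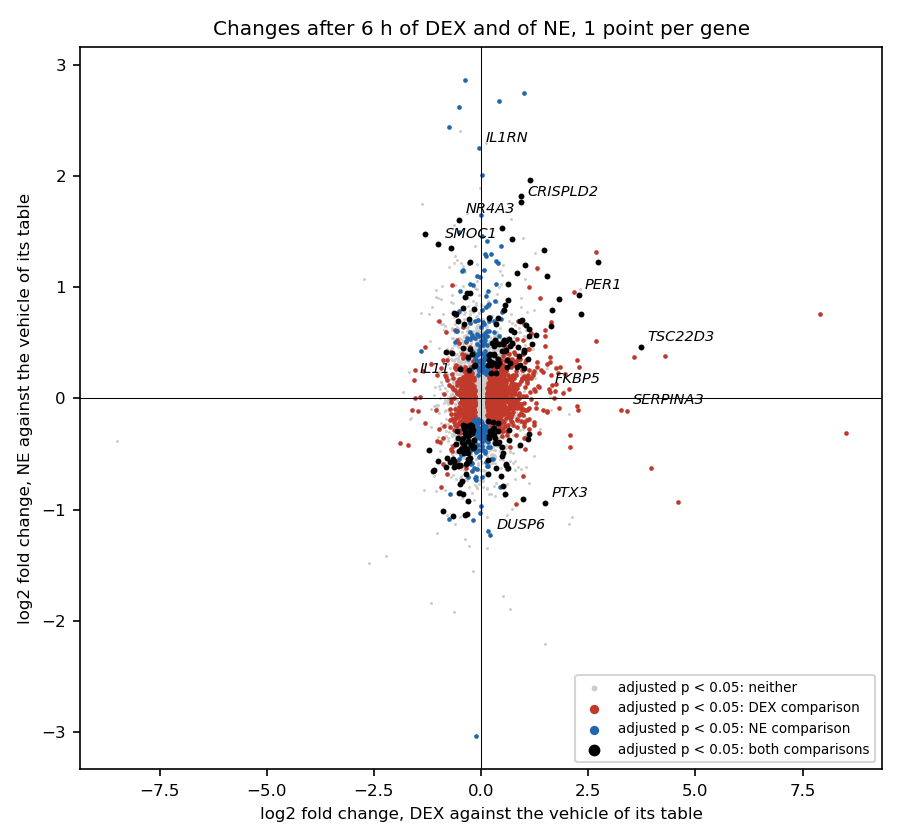
Log2 fold change of each gene tested in both comparisons, DEX on the horizontal and NE on the vertical axis. Colours mark genes with an adjusted p below 0.05 in the DEX comparison, the NE comparison or both, and genes with few counts make up the points farthest out on the horizontal axis. DUSP5 lies at 0.97 and -0.90, and CRISPLD2 at 0.94 and 1.77.

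The vehicle libraries of the 2 tables, which received the same nominal treatment, differed in 7460 of 15319 genes, 3742 higher and 3718 lower in the NE table. The following genes were chosen after their values were seen. The stress proteins HSPA6 and HSPA1A were 52.6-fold and 8.75-fold lower in the NE table's vehicle libraries (adjusted p = 1.9e-08 each), and heme oxygenase 1 (HMOX1) was 16.9-fold lower, at 24.4 ± 0.82 against 413 ± 41 CPM. HSPA1A has a near-identical neighbour, so its own level is uncertain. LTBP1 was 7.03-fold higher, at 340 ± 9.0 against 48.3 ± 1.3 CPM. FOS and NR4A1 were 5.97-fold and 7.27-fold lower, and IL6 was 5.71-fold lower. The batch and the treatment cannot be told apart in any direct comparison of DEX with NE libraries, and setting within-table effects against each other removes a shift common to a table but not a response that depends on the table.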

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

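The test of the difference between the DEX and NE effects was chosen after the data were seen, because the tables hold different vehicle libraries. The 61 genes called in opposite directions by DEX and NE all had effects that differed by that test (edgeR's quasi-likelihood test, adjusted p below the threshold for each). They were chosen for opposite calls in the same libraries, so this test largely restates that choice and is no independent evidence. Of the first 5 by the naming rule, 4 are given here, with the DEX effect minus the NE effect on the log2 scale. SMOC1, a calcium-binding matrix protein, differed by -2.38 (SE 0.08), as it was lower with DEX and higher with NE. F3, the initiator of blood clotting, differed by 1.425 (SE 0.09), and the ERK phosphatase DUSP5 by 1.865 (SE 0.10). The matricellular protein CCN1 differed by 0.974 (SE 0.07), and these 3 genes were higher with DEX and lower with NE. No outlier test was made, since each group has 3 libraries.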

How the results depend on the processing

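The fit of all 12 libraries, the GC and length correction, the block combined with another choice, and every test of the difference between the effects or of the vehicle libraries were chosen after the data were seen. The direct comparison of DEX with NE libraries was not run, and fitting only the compared groups equals the fit within a table. The DEX count of 1530 genes was 983 to 1835 with single libraries left out, 1066 with the replicate block, and within 1.5 times in the other settings. The NE count of 441 was 1688 with the replicate block, 839 with the GC and length correction, 2165 with both, 702 in the fit of all 12 libraries, and 150 to 658 with single libraries left out. Genes called in the same direction by both treatments (137) numbered 241 with the replicate block, 240 with the correction, 388 with both, and 59 to 170 with single libraries left out. Genes called in opposite directions (61) numbered 113 with the block, 130 with the correction, 205 with both, 92 without a filter on low counts, 97 in the fit of all 12 libraries, and 29 to 99 with single libraries left out. The cause of these changes was not tested, beyond the tests of the NE count given among the other observations. With an estimated correlation camera called 2 lists for DEX, 3 for NE and 2 for the difference in place of 16, 16 and 18, and with the replicate block as well 1, 0 and 4. Fry did not call some lists that camera called. With DEX these were interferon-stimulated genes (fry adjusted p = 0.123) and ribosomal protein genes (0.317). With NE they were extracellular matrix (0.217), inflammatory genes (0.0754), interferon-stimulated genes (0.0975) and the unfolded protein response (0.0754). The others with NE were steroid receptors and chaperones (0.132), cholesterol synthesis, epithelial markers and adrenergic receptors (0.0729 each). For the difference fry did not call cAMP and CREB targets, cAMP signalling components, inflammatory genes, the unfolded protein response and mitochondrially encoded genes (0.0806 to 0.241). Fry alone called phagocytosis (0.0151) and actin (0.0374) higher with DEX. With NE it alone called phagocytosis lower (0.00452) and trabecular meshwork markers higher (0.0101). Beyond the NE calls given with the block above, and PLAU, whose NE call it ended, the block changed no NE call of a list or a gene chosen by the naming rule. The replicate numbers do not pair the DEX table, where no vehicle library correlated best with its own number. With the block, and with the correction as well, FOS and IL6 were called with DEX. Ribosomal protein genes turned with NE, called higher without vehicle replicate 1 (camera adjusted p = 0.0138) and lower in 4 settings, with 6.17e-05 to 0.708 over all single libraries left out. The difference between the effects (957 genes) and the vehicle difference (7460 genes) stayed within 1.5 times in each setting run. With 19326830 to 36216506 counts per library, genes such as MYOC, ANGPTL7 and (in the DEX table) ADRB1 had too few counts to test.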

Other observations

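The tests of the ERK list's members with NE and of its difference between the effects, of glucocorticoid receptor activity with NE, of the GC and length correction as the whole cause, of the shared replicate numbers and of the other splits of the samples were chosen after the results they bear on were seen. Some named genes of lists that did not pass as a whole changed after DEX in each of the 15 settings run. The cystine transporter SLC7A11 rose 1.45-fold (SE 0.05 on the log2 scale, adjusted p = 2.72e-06 by edgeR) and the transcription factor CEBPB 1.33-fold (adjusted p = 2.69e-05). In the hypoxia and glycolysis list NDRG1 rose 1.43-fold and hexokinase 2 (HK2) 1.31-fold, while the glucose transporter SLC2A3 fell by 0.47 on the log2 scale (SE 0.08). The kinase anchor AKAP12 rose 1.61-fold, the cytoskeletal adaptor PDLIM1 1.38-fold, and CNN1, a smooth muscle calponin, fell by 0.33 (SE 0.05). KDR, a VEGF receptor, rose 1.81-fold from 1.64 ± 0.049 CPM (SD, n = 3; edgeR adjusted p = 0.00581). SLC7A11 also rose with NE (1.43-fold), and the difference between the effects did not pass (0.02, SE 0.08, adjusted p = 0.952).

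The vehicle libraries of the 2 tables differed in 7460 genes. Depth does not account for this, since 7000 genes were called after thinning to the lowest total. A count this high also argues against the same libraries only sequenced again and counted in the same way. GC content and length explained 3.8% of the variance of the log2 differences, which argues against them as the main source. Pseudogenes made up 2.37% of the genes that differed and 4.65% of the genes tested. With so few tested they could not have made up most of the genes that differed. That share therefore does not decide whether reads were assigned to pseudogenes differently in the 2 tables. A difference in culture, day or library preparation may lie behind it, which the labels give no means to test, and no biological explanation was tested. Of the 10 splits of these 6 libraries 1, the real one, gave as many genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

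The list of the glucocorticoid response rose with NE. Its 2 members shared with the cAMP and CREB list do not account for this alone, since the other 22 were still called (p = 0.000501 with an estimated correlation, median log2 fold change 0.11). Whether glucocorticoid receptor activity contributes cannot be told apart from other causes here. The 108 genes that DEX raised over 2-fold outside the cAMP list had a median log2 fold change of 0.199 with NE (interval 0.11 to 0.26 from a bootstrap over these genes), with 15 called higher and 3 lower. This interval spans the bound of 0.2 set for the test. Genes measured in the same libraries are not independent replicates, so the interval does not measure the spread between libraries. Targets that both cAMP and glucocorticoids raise may be part of the list, and this remains untested.

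The number of genes called with NE rose from 441 to 1688 with the replicate number as a block. The tables argue against depth, since the ratio of the counts was 4.1 after thinning, and GC content and length are not the whole cause, since the ratio was 2.58 after their correction. They explained 43.8% of the variance of the shared deviation of the libraries numbered 1, between the bounds set for the test, so their part cannot be told apart from a shared preparation. A candidate explanation is that equal numbers share a culture or preparation, as each same-numbered pair correlated (lowest 0.267). Deviations from a mean of 3 libraries cancel, so one shared by the libraries numbered 1 alone pushes the correlations among numbers 2 and 3 upward. The pairs numbered 2 and 3 are therefore not separate support for this explanation. Vehicle 2 correlated more with NE replicate 3 (0.346), and vehicle 3 also correlated with NE replicate 2 (0.149). For numbers 2 and 3 the check therefore cannot tell this pairing from the swapped one. The vehicle numbers come from column names alone.

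A hypothesis is that NE lowered the output of the ERK pathway, which induces its own inhibitors. It arose from seeing DUSP6, SPRY4 and CCND1 among the largest decreases, so the list written for it holds genes already seen. All 10 members gave a camera p of 0.00278 with an estimated correlation and a median of -0.61, with 9 called lower. That first test was replaced, when its result and all members' values were known, by one on the 5 members not seen when the list was written (PHLDA1, DUSP4, EPHA4, ETV4 and ETV5). Camera with an estimated correlation gave p = 0.0329 for these, with a median of -0.46, and 4 of them were called lower. The ERK list was not tested with the replicate block. With that block and an estimated correlation no fixed list was called with NE. DUSP4 is also among the immediate early genes. These values are consistent with lower ERK output, which was not measured. Whether the decrease was of the same size in the DEX table is not decided here. The difference between the effects gave a camera p of 0.00904 for the list with an estimated correlation, with a median of 0.55 and 6 of 10 members called higher under DEX than under NE and 0 lower. The members already seen were picked for their fall with NE, which enters this difference and favours a positive value. Of the 5 members not seen before, DUSP4 was called (0.59, SE 0.14, adjusted p = 0.0281). The other members not seen before were not (adjusted p from 0.0642 to 0.971). Whether the list falls at all with DEX as a set stays open. The list did not pass there (camera p = 0.563 with an estimated correlation). Its median was 0.036, over the bound of 0 set beforehand, but that bound was wrong for members that move both ways (EPHA2, PHLDA1 and CCND1 were called lower and EPHA4 higher), where a median decides nothing.

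Of the 10 splits of the 6 libraries in each table, 1 gave as many genes as the real one with DEX (1530, highest other 2) and 1 with NE (441, highest other 1), and 10 splits are too few for a share under 0.05. For the difference between the effects, 1 of 60 splits drawn within the tables, the real one, gave as many genes as 957, and the highest other gave 364. That count of splits leaves mirrored labels within a table out, a choice made after a first draw was seen, since reversing one table's labels tests the sum of the effects in place of their difference. The 6 splits that kept the DEX groups gave 307 to 364 genes, the 6 that kept the NE groups at most 55, and the 47 others at most 1. Each split other than the real one breaks up the groups of 1 or both treatments. The share of splits therefore does not test whether the 2 effects are equal.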
